A study of Homo sapiens with 35 samples.

How the data were processed

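RNA of 35 samples of RPMI8226 cells was sequenced after 24 h of treatment, in the 12 groups described below. Per the labels' protocols, cells were treated in 12-well plates, total RNA with an integrity number above 7 went into directional mRNA libraries (MGIEasy, 500 ng of input), and these were read as 100 bp pairs on an MGI sequencer. The deposited table holds 1 expected count per Ensembl gene and library. Per the submitters' processing notes, the authors made these expected counts with FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on GRCh38. The order of these steps, their settings and the annotation release are not given in the labels. The values are at least 0, and from 9.10 to 10.4% of those in a library are not whole, as RSEM shares reads between transcripts. The table has 60675 genes and 35 columns, each matched to its sample by the code in that sample's description, and no column was left over.

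Counts were rounded to whole numbers and analysed in R 4.3.3. A table pairing gene identifiers with current symbols gave a symbol to 56558 genes (93.2%). Coordinates, gene types and exon lengths came from GENCODE release 29 on GRCh38, which holds 17897 of the 18025 genes tested (99.3%). Groups and replicate numbers were taken from the sample titles. Total expected counts were 29470114 to 31663025 in vehicle, 28411511 to 31236741 in BJIKT 500, 30213629 to 36155451 in BJIKT 125, 30894714 to 32966610 in Panax ginseng 500, 26934793 to 30754581 in Panax ginseng 125, 22787301 to 29535979 in Astragalus 500, 25272205 to 28173110 in Astragalus 125, 25542642 to 35624339 in Atractylodes 500, 30790349 to 33692329 in Atractylodes 125, 29698140 to 32151819 in Glycyrrhiza 500, 32447206 to 35481653 in Glycyrrhiza 125 and 28237092 to 33620869 in mixture. At the lowest of these depths, 1 CPM stands for 22.8 counts. Where a group had almost no reads for a gene, its summed counts were compared instead, with an exact conditional 95% interval of the ratio. These intervals cover counting error only.

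Genes were kept by filterByExpr of edgeR 4.0.16 with its defaults (minimum count 10, minimum total 15), which left 18025 genes. Libraries were scaled by TMM, and 1 robust quasi-likelihood fit of all 35 libraries with a mean per group gave every comparison, with 23 residual degrees of freedom. The common dispersion was 0.00708, a biological coefficient of variation of 8.42%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. There were 18 comparisons, fixed before the data were examined: each of 11 treated groups against the vehicle, 5 dose contrasts, the mixture against BJIKT at 500 µg/mL, and the mixture's log2 fold change against the sum of those of the 4 single herbs at 125 µg/mL. The labels do not say whether replicates were separate cultures grown on separate days, so p-values measure only the spread between these samples. That spread was estimated per gene over all 12 groups together, though the groups were unequal. The chi-square between 2 replicates' counts, per degree of freedom, was 2.98 to 3.95 in Panax ginseng 500 and up to 77.2 in the mixture. A shared spread can give too many calls in uneven groups and too few in even ones. CPM values use TMM-scaled library sizes. SE values were worked back from the test, as the size of the log2 fold change divided by the square root of its F statistic.

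In the same way, 39 gene lists were fixed beforehand, and lists with at least 3 tested members were tested with camera of limma 3.58.1. The inter-gene correlation was preset at 0.01, and adjustment ran over the lists of a comparison. An estimated correlation was tried beside it. The estimate was above the preset for many lists, and camera adjusted p values then rose by many orders of magnitude. For the MHC class II list with BJIKT 500 the estimate was 0.163, and the camera adjusted p went from 5.25e-27 to 2.62e-06. Camera values below use the preset, and those with the estimate are printed only where a list no longer passed. Each list's members were also adjusted over the list alone. For named genes the rule was as follows. In BJIKT, mixture and single-herb comparisons at 500 µg/mL, up to 12 higher and 12 lower called genes with the largest log2 fold changes could be named, and up to 5 each way elsewhere. They needed a mean of at least 2 CPM, a symbol of a gene that is not a clone or pseudogene, and every library of one group beyond every library of the other. Up to 4 called members with the smallest adjusted p per list and comparison were named as well, or the member with the smallest p where none was called, and markers in the vehicle. Not every gene that the rule allows is printed. Reads of AKR1C1 to AKR1C3, C4A and C4B, HSPA1A and HSPA1B, RN7SL1 and RN7SL2, the POTE family, HLA genes, metallothioneins and EIF3CL are shared between near-identical copies, so their split between copies is uncertain.

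Each comparison was repeated with DESeq2 1.42.0, with RLE scaling, without the low-count filter, with the replicate number as a block, in a fit of only the groups compared, and without each of its libraries in turn. After the libraries were inspected, 2 settings were added: removal of a per-library trend of log2 CPM with log2 exon length (a spline with 4 degrees of freedom, from genes above 1 CPM), and omission of Panax ginseng 125 replicate 1 and mixture replicate 2. Similarity of profiles was set against 20 simulations of unchanged groups that shared a simulated vehicle, with each gene drawn independently. The fit was tested on simulated data drawn at the real means and depths. For BJIKT 500 against the vehicle, over 17564 genes, it recovered 77.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and all of those changed 4-fold, with 7 false calls (21 in DESeq2). For Panax ginseng 125 with its 2 libraries, over 17555 genes, it recovered 56.7%, 91.0% and 98.5%, with 12 false calls (21 in DESeq2). Simulated libraries varied by 1 dispersion per gene that all groups shared. The real Panax ginseng 125 libraries differed far more, with a chi-square per degree of freedom of 75.6 against 2.98 to 3.95 within Panax ginseng 500. These false calls are therefore no error rate for the real Panax ginseng 125 comparison. The camera test called the changed list in both and no other of the 37 tested. The simulated genes were independent, so this does not test camera on lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9.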

Results

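RPMI8226 is an established human myeloma line with the features of antibody-secreting plasma cells. Bojungikki-tang (BJIKT) is a traditional herbal decoction. RNA sequencing measured gene expression in RPMI8226 cells after 24 h with a water extract of BJIKT, with an extract of 1 of 4 of its ingredient herbs (Panax ginseng, Astragalus, Atractylodes or Glycyrrhiza), with a mixture of the 4, or with PBS as the vehicle. The series asks how BJIKT acts on immune gene expression. BJIKT and each herb were given at 500 and 125 µg/mL, and the mixture held 125 µg/mL of each herb, or 500 in all; per the labels, viability was not affected at these doses. Each of the 12 groups had 3 libraries except Panax ginseng 125, which had 2, giving 35 libraries. Total expected counts ran from 22787301 in Astragalus 500 replicate 1 to 36155451 in BJIKT 125 replicate 3, with a median of 30894714, and 18025 genes were tested. Levels are given as mean ± SD in CPM, which are counts scaled to library size, and log2 fold changes ± SE come from 1 edgeR fit of all libraries.

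The sample codes carried a middle number of 1, 2 or 3, called the code set here, whose meaning the labels do not give. Code set 1 held the vehicle, both BJIKT doses and Panax ginseng 500. Code set 2 held Panax ginseng 125, both Astragalus doses and Atractylodes 500, and code set 3 held the rest. Only BJIKT and Panax ginseng 500 against the vehicle, and the dose contrasts of BJIKT, Astragalus and Glycyrrhiza, compare libraries of 1 code set. In every other comparison the code set changes along with the treatment. The leading principal component took 19.2% of the variance. Of that component's variance, 97.1% lay between groups and 65.5% between code sets.

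Vehicle cells expressed most of the listed plasma cell genes, along with some markers of other cell types. Of 20 plasma cell genes, 18 exceeded 10 CPM in the 3 vehicle libraries. These included the joining chain JCHAIN at 4889 ± 93.5 CPM, the secretory-pathway disulfide isomerase TXNDC5 at 3882 ± 86.5 CPM and the syndecan SDC1 at 231 ± 3.00 CPM. The lambda light chain IGLC2 stood at 3753 ± 121 CPM against 116 ± 13.7 CPM for the kappa chain IGKC. The B cell transcription factor PAX5 stood at 0.601 ± 0.170 CPM, and 7 of 14 B cell identity genes were below 1 CPM. So were 8 of 12 T cell, 10 of 12 myeloid, 9 of 9 hepatocyte, 6 of 8 fibroblast and 2 of 8 epithelial marker genes. However, 5 of 14 B cell identity genes and 5 of 8 epithelial markers exceeded 10 CPM. So did 2 of 12 myeloid, 1 of 12 T cell and 1 of 8 fibroblast markers, the T cell one being CD28, which is also in the plasma cell list. Among these were the complement receptor CR2 at 139 CPM, the adhesion molecule EPCAM at 86.3 CPM and the fibronectin FN1 at 3129 CPM.

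BJIKT at 500 µg/mL gave its largest rises in chemokine and antigen presentation genes. CXCL10, a chemokine that attracts activated T cells, went from 3.24 ± 0.179 to 59.9 ± 9.79 CPM, a log2 fold change of 4.21 ± 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.06e-21). Its neighbour CXCL9 rose by 3.76 ± 0.12 and the cytokine IL32 by 3.09 ± 0.26. In GRCh38 coordinates of GENCODE release 29, CXCL10 (ENSG00000169245) spans chromosome 4, 76021117 to 76023497, and CXCL9 chromosome 4, 76001275 to 76007488. Of 11 MHC class II presentation genes, 9 rose (9 adjusted over the list alone), with a median log2 fold change of 1.68 (camera adjusted p = 5.25e-27). HLA-DRA (chromosome 6, 32439842 to 32445046) rose by 2.48 ± 0.088, the peptide loaders HLA-DMA and HLA-DMB by 1.58 and 1.62, and the invariant chain CD74 by 0.92. Of 20 NF-kB targets, 13 rose (15 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1e-26), among them NFKB2 at 1.44, BIRC3 at 1.48, RELB at 1.36 and CXCL8 at 1.69. The cytokine receptor chain IL2RG rose by 1.93. Every library of BJIKT 500 lay beyond every vehicle library for CXCL10, CXCL9, IL32, HLA-DRA and IL2RG. The rule for naming the largest changes required this, so it is no added support.

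The same dose of BJIKT raised oxidative stress genes. Of 19 NRF2 targets, 17 rose (17 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 6.55e-31). AKR1C2 rose by 1.76, the quinone reductase NQO1 by 1.14, the haem oxygenase HMOX1 by 0.91 and the autophagy receptor SQSTM1 by 0.90. The ferritin chains FTH1 and FTL rose by 0.90 and 0.72. Of 25 ATF4 targets, 12 rose (13 adjusted over the list alone; camera adjusted p = 6.07e-06), including the serine and asparagine synthesis enzymes PHGDH at 0.73 and ASNS at 0.52. Lipid synthesis genes went the other way. Of 24 cholesterol synthesis genes, 7 fell and 1 rose (10 called when adjusted over the list alone; camera adjusted p = 6.41e-05), with HMGCS1 at -0.48. Of 13 fatty acid synthesis genes, 8 fell (8 adjusted over the list alone; camera adjusted p = 0.000335, but 0.143 as the adjusted p with an estimated correlation), with FADS1 at -0.41 and ACLY at -0.35. TXNDC5 fell by 0.81 ± 0.057 to 2219 ± 54.9 CPM, and the survival receptor TNFRSF17 fell by 0.64. The plasma cell list as a whole did not pass (camera adjusted p = 0.063). It did pass with RLE scaling (camera adjusted p = 0.0464), with the replicate number as a block (camera adjusted p = 0.0379) and with a trend of exon length removed (camera adjusted p = 0.00527). The largest falls were in the potassium channel KCNQ3 at -1.37 and the secreted factor ANGPTL2 at -1.35, and the transcription factor KLF2 fell by 0.99.

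In all, 2554 genes were called with BJIKT 500, 1491 higher and 1063 lower, 237 of them at least 2-fold. Leaving out 1 library moved this count to 1371 without vehicle replicate 2, 1085 without vehicle replicate 3, 1179 without BJIKT 500 replicate 1, 896 without BJIKT 500 replicate 2 and 4100 without BJIKT 500 replicate 3; without both Panax ginseng 125 replicate 1 and mixture replicate 2, libraries that stood apart, it was 5028. The higher share was 58.4%, and 47.1% after a trend with exon length was removed from each library. Also, 7 of 34 cytosolic ribosomal protein genes and 10 of 31 respiratory chain genes were higher (23 and 17 adjusted over the list alone), but both lists had an adjusted p = 0.458 with an estimated correlation.

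At 125 µg/mL BJIKT moved 56 genes, of which 45 were higher. CXCL10 rose to 12.3 ± 0.422 CPM, by 1.93 ± 0.13 on the log2 scale, CXCL9 by 1.68, IL2RG by 1.03 and HLA-DRA by 0.96. A total of 5 of 20 NF-kB targets (7 adjusted over the list alone; camera adjusted p = 3.37e-20) and 3 of 11 class II genes rose (3 adjusted over the list alone; camera adjusted p = 1.81e-09). Falls were seen in LSS and ACSS2, of sterol and acetyl-CoA synthesis, at -0.28 and -0.24 (neither called without the low-count filter, and without 1 library ACSS2 lost its call in 6 of 6 fits and LSS in 5 of 6), and TXNDC5 fell by 0.34. Set against each other, 500 exceeded 125 µg/mL by 2.28 for CXCL10, 2.27 for IL32 and 1.53 for HLA-DRA, and 8 of 11 class II genes (9 adjusted over the list alone; camera adjusted p = 5.72e-27) and 11 of 19 NRF2 targets were higher at 500 (17 adjusted over the list alone; camera adjusted p = 6.49e-31). At 500, TNFRSF17 was lower by 0.55. The dose contrast called 370 genes, 257 higher at 500. Against the vehicle the count moved to 29 without vehicle replicate 2, 30 without vehicle replicate 3, 37 without BJIKT 125 replicate 2 and 28 without BJIKT 125 replicate 3, to 221 with no low-count filter, 107 in a fit of these groups only and 118 without both unusual libraries. The dose count moved to 141 without BJIKT 125 replicate 1, 201 without BJIKT 125 replicate 2, 157 without BJIKT 500 replicate 1, 144 without BJIKT 500 replicate 2 and 1452 without BJIKT 500 replicate 3, and was 657 with DESeq2, 1293 without the filter, 102 in a fit of both doses alone and 2183 without both unusual libraries. Its higher share of 69.5% became 38.6% without the filter, 37.5% without both unusual libraries, 40.6% without BJIKT 500 replicate 3, 53.7% in DESeq2, 56.6% after removal of the length trend and 82.4% in the fit of both doses alone.

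Panax ginseng at 500 µg/mL raised chemokine, class II and NF-kB genes. CXCL10 reached 71.7 ± 5.30 CPM, a rise of 4.47 ± 0.12, CXCL9 rose by 3.93 ± 0.12 and the B cell follicle homing receptor CXCR5 by 4.11 ± 0.93, though CXCR5 was not called in DESeq2, in a fit of both groups alone or in 3 of 6 fits without 1 library. Of 11 class II genes, 10 rose (10 adjusted over the list alone), with a median of 1.52 (camera adjusted p = 3.22e-38), HLA-DRA by 1.71. Of 20 NF-kB targets, 11 rose and 1 fell (18 called when adjusted over the list alone; camera adjusted p = 4.51e-62), with BIRC3 at 1.29, CXCL8 at 1.97 and the activation marker CD83 at 0.83. Of 19 NRF2 targets, 8 rose (16 adjusted over the list alone; camera adjusted p = 2.34e-34), as did 4 of 16 heat shock genes (8 adjusted over the list alone; camera adjusted p = 1.16e-13), HSPA1A by 0.74 and DNAJB1 by 0.46. The mTOR inhibitor DDIT4 fell by 1.06 ± 0.20. Of 25 hypoxia and glycolysis genes, 5 fell (14 adjusted over the list alone; camera adjusted p = 3.92e-12, but 0.0615 as the adjusted p with an estimated correlation), with the demethylase KDM3A at -0.58, the glucose transporter SLC2A3 at -0.53 and NDRG1 at -0.48. Among plasma cell genes TXNDC5 fell by 0.58, TNFRSF17 fell by 0.58 and DERL3 fell by 0.35, 4 of 20 in all (4 adjusted over the list alone; camera adjusted p = 1.01e-06). The comparison called 289 genes, 178 of them higher. The count was 445 without the filter, 1884 in a fit of both groups alone and 592 without both unusual libraries, and the higher share went from 61.6% to 51.2% without the length trend.

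Panax ginseng at 125 µg/mL, with 2 libraries, raised CXCL10 to 28.3 ± 5.28 CPM, by 3.12 ± 0.13, the cytokine LTB by 1.55 and CXCL8 by 1.49 (CXCL8 not called in a fit of both groups alone). HLA-DRA rose by 0.79, but the class II list did not pass (camera adjusted p = 0.107). The comparison called 7521 genes, 3755 higher (49.9%, but 96.2% in a fit of these groups alone). Both libraries lie in another code set than the vehicle and held reads over 33.3 and 27% of the genes with no vehicle count. The higher genes included 33 of 34 ribosomal protein genes (34 adjusted over the list alone; camera adjusted p = 2.72e-20, but 0.417 as the adjusted p with an estimated correlation) and 26 of 31 respiratory chain genes (26 adjusted over the list alone; camera adjusted p = 1.21e-14, but 0.417 as the adjusted p with an estimated correlation). In the same libraries the small nuclear RNA 7SK stood at 37.8 ± 14.8 CPM against 7.71 ± 2.26 in the vehicle, and the RNase P RNA RPPH1 rose by 2.60, a call lost without replicate 1. Replicate 1 had the steepest slope against exon length, -0.322 log2 units per doubling, and the count was 1133 without Panax ginseng 125 replicate 1; the fit of these groups alone called 393. Between doses, 500 exceeded 125 µg/mL by 1.99 for CXCL9, 1.35 for CXCL10 and 0.92 for HLA-DRA, and MHC class II transactivator CIITA by 1.65, among 6419 genes called. That count was 575 without Panax ginseng 125 replicate 1, 30 in a fit of both doses alone, without HLA-DRA and CIITA, and 1008 without both unusual libraries.

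**Figure D1:**
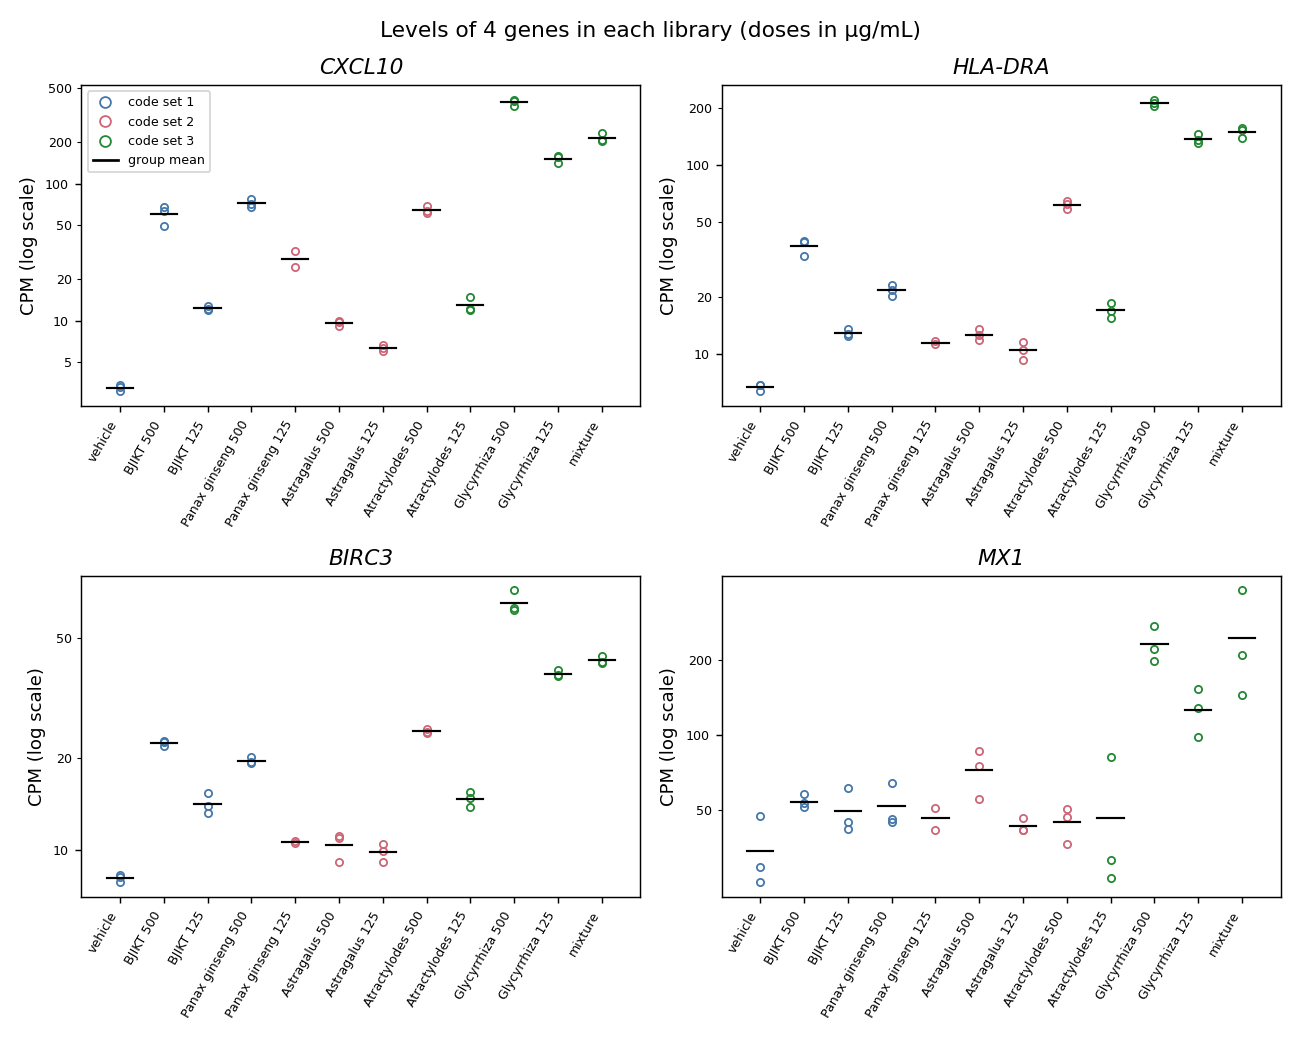
Level of CXCL10, HLA-DRA, BIRC3 and MX1 in each library, in CPM on a log axis, by treatment group with doses in µg/mL. Circles are libraries coloured by code set and bars are group means. CXCL10 lay above the vehicle in every treated library and was highest with Glycyrrhiza 500, at 393 ± 21.6 CPM.

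Astragalus at 500 µg/mL lowered lipid synthesis genes. Of 24 cholesterol synthesis genes, 19 fell and 1 rose (21 called when adjusted over the list alone), with a median of -0.27 (camera adjusted p = 2.04e-20). HMGCS1, at the head of the pathway, fell by 0.76 ± 0.073, the squalene epoxidase SQLE fell by 0.62, LSS fell by 0.65 and INSIG1 fell by 0.45. Of 13 fatty acid synthesis genes, 9 fell and 1 rose (10 called when adjusted over the list alone; camera adjusted p = 1.04e-10), ACSS2 fell by 0.65 and the desaturase FADS2 fell by 0.47. The aryl hydrocarbon receptor target CYP1A1 fell by 2.53 ± 0.39. Of 20 plasma cell genes, 9 fell and 2 rose (13 called when adjusted over the list alone; camera adjusted p = 0.000404), with TXNDC5 at -0.88, TNFRSF17 at -0.67 and the transcription factor IRF4 at -0.36. Immune genes also rose. CXCL10 rose by 1.56 ± 0.13 to 9.60 ± 0.390 CPM and HLA-DRA by 0.93, and 4 of 11 class II genes were called (5 adjusted over the list alone; camera adjusted p = 0.000348, but 0.0753 as the adjusted p with an estimated correlation). Of 23 type I interferon genes, 7 rose (8 adjusted over the list alone; camera adjusted p = 4.31e-06, but 0.271 as the adjusted p with an estimated correlation), ISG15 by 1.25. Of 19 NRF2 targets, 9 rose (13 higher and 1 lower when adjusted over the list alone; camera adjusted p = 5.33e-11), NQO1 by 1.15. The hormone precursor POMC rose by 1.57. RPPH1 rose by 2.63 and 7SK by 2.08, and 21 of 34 ribosomal protein genes were higher (26 adjusted over the list alone; camera adjusted p = 6.58e-13, but 0.261 as the adjusted p with an estimated correlation), in libraries that also held reads over genes with no count in the vehicle. This comparison called 2787 genes, 1743 higher. That became 1681 without vehicle replicate 2, 1419 without vehicle replicate 3, 1710 without Astragalus 500 replicate 2 and 1730 without Astragalus 500 replicate 3, 5723 in a fit of both groups alone (48.7% higher against 62.5%) and 4869 without both unusual libraries.

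At 125 µg/mL Astragalus gave 3703 calls, 2191 higher. RPPH1 at 2.81 and 7SK at 2.44 (not called in a fit of both groups alone) led them, with 28 of 34 ribosomal protein genes (29 adjusted over the list alone; camera adjusted p = 3.43e-17, but 0.504 as the adjusted p with an estimated correlation). The Astragalus 125 libraries lie in another code set than the vehicle. They held reads over 23.6 to 28.8% of the genes with no vehicle count, so these rises cannot be ascribed to the extract alone. CXCL10 rose by 0.96 and HLA-DRA by 0.65, while 8 of 24 cholesterol synthesis genes fell and 1 rose (12 called when adjusted over the list alone; camera adjusted p = 0.061). Between both doses, which share a code set, 10 of 24 cholesterol genes were lower at 500 (18 adjusted over the list alone; camera adjusted p = 6.97e-27), with HMGCS1 at -0.53 ± 0.073 and SQLE at -0.38. TNFRSF17 was lower by 0.93 ± 0.12, TXNDC5 was lower by 0.60 and the muscle protein gene MYOM2 was lower by 1.15, and 3 of 16 heat shock genes were lower (11 adjusted over the list alone; camera adjusted p = 1.15e-14). AKR1C2, HMOX1 and the cadherin CDH1 were higher at 500, by 0.75, 0.45 and 0.96. The dose contrast called 147 genes, 77 higher. Against the vehicle the 125 count moved to 2120 without vehicle replicate 2, 1721 without vehicle replicate 3, 2099 without Astragalus 125 replicate 1 and 2116 without Astragalus 125 replicate 2, 6200 in a fit of both groups alone and 5924 without both unusual libraries. The dose count moved to 68 without Astragalus 125 replicate 1, 80 without Astragalus 125 replicate 2, 67 without Astragalus 125 replicate 3, 89 without Astragalus 500 replicate 1, 65 without Astragalus 500 replicate 2 and 89 without Astragalus 500 replicate 3, and to 279 with DESeq2 (38.0% higher against 52.4%), 396 without the filter (65.2% higher), 1476 in a fit of both doses alone and 546 without both unusual libraries.

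Atractylodes at 500 µg/mL raised IL32 by 4.68 ± 0.23, CXCL9 by 4.48 ± 0.12 and CXCL10 by 4.30 ± 0.12. Of 11 class II genes, 10 rose (10 adjusted over the list alone), with a median of 3.22 (camera adjusted p = 1.51e-53), HLA-DPA1 by 3.42 and HLA-DRA by 3.22 to 61.9 ± 3.26 CPM. Of 20 NF-kB targets, 13 rose and 1 fell (18 called when adjusted over the list alone; camera adjusted p = 1.36e-29), with LTB at 2.16, BIRC3 at 1.61 and TNFAIP3 at 1.33. The metal-binding MT2A rose by 2.04 and the TNF family ligand CD70 by 1.61. Of 25 ATF4 targets, 17 rose and 1 fell (19 called when adjusted over the list alone; camera adjusted p = 1.04e-10), with the glutathione-degrading enzyme CHAC1 at 1.73 ± 0.20, PSAT1 at 0.70 and DDIT4 at -1.07. Of 16 heat shock genes, 12 rose (12 adjusted over the list alone; camera adjusted p = 1.26e-09), and 11 of 24 cholesterol synthesis genes rose while 1 fell (12 called when adjusted over the list alone; camera adjusted p = 0.00847, but 0.172 as the adjusted p with an estimated correlation). The mucin gene MUC16 fell by 1.18 and the Toll-like receptor homologue CD180 fell by 1.24. Several POTE family genes led the falls, POTEB2 at -1.67, but reads of this family are shared between near-identical copies. This comparison called 4379 genes, 2598 higher, and the count was 2869 without vehicle replicate 2, 2640 without vehicle replicate 3 and 1958 without Atractylodes 500 replicate 1. Replicate 1 was unlike the other replicates. It held reads over 24.4% of the genes with no vehicle count, against 8.49 and 8.21% in replicates 2 and 3. Its slope against exon length was -0.165 log2 units per doubling, against -0.0913 and -0.0926.

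At 125 µg/mL Atractylodes raised CXCL9 by 2.28, CXCL10 by 2.00 ± 0.13, HLA-DRA by 1.35, LTB by 1.23 and IL2RG by 1.18. A total of 7 of 20 NF-kB targets (12 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.37e-22) and 4 of 25 ATF4 targets rose (9 adjusted over the list alone; camera adjusted p = 1.89e-09), CHAC1 by 1.09 (not called without Atractylodes 125 replicate 3 or vehicle replicate 1), and CD180 fell by 0.74. The 500 dose exceeded 125 by 2.54 for IL32, 2.26 for HLA-DPA1 and 2.31 for CXCL10, and 9 of 11 class II genes were higher (10 adjusted over the list alone; camera adjusted p = 9.61e-65). Calls came to 80 genes at 125 and 346 between doses. The first count moved to 38 without vehicle replicate 1, 39 without vehicle replicate 2, 41 without vehicle replicate 3, 48 without Atractylodes 125 replicate 2 and 38 without Atractylodes 125 replicate 3, to 178 with DESeq2, 354 without the filter, 832 in a fit of both groups alone and 292 without both unusual libraries, with 88.8% higher against 45.2% in that fit of both groups, 48.3% without the filter, 71.9% without both unusual libraries and 76.7% after removal of the length trend. The count between doses moved to 81 without Atractylodes 125 replicate 1, 230 without Atractylodes 125 replicate 2, 107 without Atractylodes 125 replicate 3 and 72 without Atractylodes 500 replicate 1, 893 with DESeq2, 1430 without the filter and 2230 without both unusual libraries.

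Glycyrrhiza at 500 µg/mL gave the most calls of the single herbs at that dose, 5898, 3196 higher and 2702 lower, 1000 of them at least 2-fold. CXCL9 rose by 6.95 ± 0.13, CXCL10 by 6.92 ± 0.13 to 393 ± 21.6 CPM, IL32 by 6.55 ± 0.21 and CXCL8 by 5.03 ± 0.16. All 11 class II genes rose (11 adjusted over the list alone), with a median of 5.01 (camera adjusted p = 4.31e-67), HLA-DRA to 214 ± 8.59 CPM, and 13 of 15 class I presentation genes rose (13 adjusted over the list alone; camera adjusted p = 7.74e-13), with the peptide transporter TAP1 at 1.14. All 23 type I interferon genes rose (23 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 3.09e-23), IFITM1 by 2.85. Of 20 NF-kB targets, 18 rose and 1 fell (19 called when adjusted over the list alone; camera adjusted p = 7.52e-64), BIRC3 by 3.02 and NFKB2 by 2.36. Some genes went from almost no reads. The cytokine subunit EBI3 had 1047 counts against 2, a ratio of 543 with a 95% counting interval of 150 to 4493, and OLFML2A had 752 counts against 1, a ratio of 781 with a 95% counting interval of 140 to 30869. The defensin DEFB4A had 476 counts against 0, where the 95% counting interval of the ratio begins at 133. The lymph node homing receptor CCR7 had 398 counts against 0, where it begins at 111.

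Metabolic and stress genes moved as well with Glycyrrhiza 500. Of 25 ATF4 targets, 22 rose (22 adjusted over the list alone; camera adjusted p = 2.87e-52), CHAC1 by 4.37 ± 0.18, PSAT1 by 2.22 ± 0.07, the mTOR regulator SESN2 by 2.16 and ASNS by 1.70. Of 19 NRF2 targets, 18 rose (18 adjusted over the list alone; camera adjusted p = 1.69e-31), AKR1C2 by 2.41 and the cystine transporter SLC7A11 by 2.04. Of 24 cholesterol synthesis genes, 17 rose and 2 fell (20 called when adjusted over the list alone; camera adjusted p = 2.85e-06), HMGCS1 by 0.79. MT2A rose by 4.55. In the plasma cell list 6 genes rose and 6 fell of 20 (14 called when adjusted over the list alone; camera adjusted p = 0.0922), with the elongation factor ELL2 at 1.56, IRF4 at 1.06 and SDC1 at -0.64. The histamine receptor HRH1 fell by 2.55, ANGPTL2 fell by 2.42, the ectonucleotidase NT5E fell by 1.98 and the chemokine receptor CXCR3, which binds CXCL9 and CXCL10, fell by 1.95. Every library of one group lay beyond every library of the other for these 4 genes, a condition of the rule for naming the largest changes. No single library moved the count of 5898 by over 1.5 times, but the vehicle was in code set 1 and Glycyrrhiza in code set 3.

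Glycyrrhiza at 125 µg/mL called 3845 genes, 2252 higher. CXCL9 rose by 5.84, CXCL10 by 5.54 ± 0.12, IL32 by 5.52 and HLA-DPB1 by 5.28, and EBI3 had 426 counts against 2, a ratio of 199 with a 95% counting interval of 54.6 to 1645. All 11 class II genes (11 adjusted over the list alone; camera adjusted p = 1.67e-92) and 21 of 23 type I interferon genes rose (22 adjusted over the list alone; camera adjusted p = 7.96e-17), the latter with a median of 1.05. Of 24 cholesterol synthesis genes, 14 rose and 2 fell (18 called when adjusted over the list alone; camera adjusted p = 1.38e-06). The signal recognition particle RNA copies RN7SL1 and RN7SL2, which cannot be separated well by reads, were lower, at -2.19 and -2.61. Neither was called in a fit of both groups alone, and each lost its call in some fits that left out 1 library. Within the code set, 500 exceeded 125 µg/mL by 2.22 ± 0.12 for CXCL8, 1.38 for CXCL10 and 1.92 for the interleukin-2 receptor chain IL2RA. At 500, 18 of 25 ATF4 targets (21 adjusted over the list alone; camera adjusted p = 1.68e-57), 12 of 23 interferon genes (20 adjusted over the list alone; camera adjusted p = 1.26e-19) and 6 of 11 class II genes were higher (10 adjusted over the list alone; camera adjusted p = 9.2e-13). Of 21 mitosis genes, 6 were lower at 500 (1 higher and 15 lower when adjusted over the list alone; camera adjusted p = 1.95e-10), with PLK1 at -0.35. TNFRSF17 was lower by 1.01 and CXCR3 was lower by 1.26. The dose contrast called 844 genes, 496 higher. The count against the vehicle moved to 2451 without vehicle replicate 3 and 2365 without Glycyrrhiza 125 replicate 1 and to 6630 in a fit of both groups alone. The dose count moved to 547 without Glycyrrhiza 500 replicate 2 and to 1342 without both unusual libraries.

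**Figure D2:**
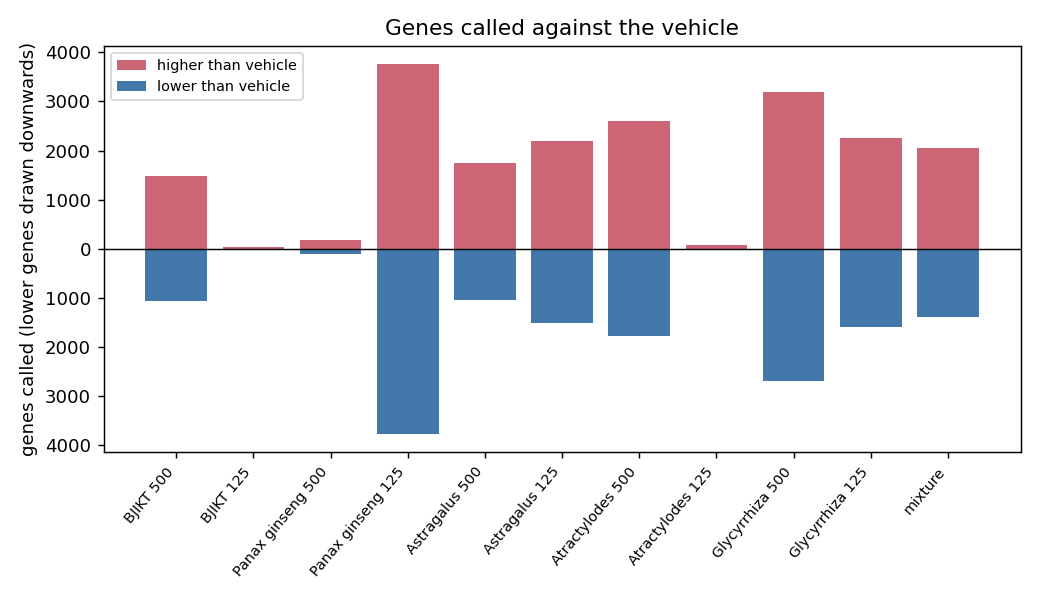
Genes called against the vehicle for each extract at each dose (µg/mL), with genes higher than the vehicle drawn upwards and genes lower drawn downwards. Bars run from 56 genes in all for BJIKT 125 to 7521 for Panax ginseng 125, where 1133 were called without its replicate 1.

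The mixture of the 4 herbs raised CXCL9 by 6.25 ± 0.12, CXCL10 by 6.05 ± 0.12 to 215.5 ± 16.8 CPM, IL32 by 5.80 ± 0.22 and CXCR5 by 4.96. EBI3 had 569 counts against 2, a ratio of 283 with a 95% counting interval of 77.9 to 2340, and OLFML2A had 392 counts against 1, a ratio of 389 with a 95% counting interval of 69.5 to 15422. Of 11 class II genes, 10 rose (10 adjusted over the list alone), with a median of 4.50 (camera adjusted p = 1.55e-95), as did 21 of 23 type I interferon genes (22 adjusted over the list alone; camera adjusted p = 6.19e-29) and 18 of 20 NF-kB targets, where 1 fell (19 called when adjusted over the list alone; camera adjusted p = 1.19e-64). Of 19 NRF2 targets, 18 rose (18 adjusted over the list alone; camera adjusted p = 3.03e-25), HMOX1 by 0.99. Of 25 ATF4 targets, 18 rose and 1 fell (19 called when adjusted over the list alone; camera adjusted p = 2.14e-21), CHAC1 by 2.87 and DDIT4 fell by 1.29. ANGPTL2 fell by 1.83, HRH1 fell by 1.54 and NT5E fell by 1.52. RN7SL2 fell by 3.05, and EIF3CL, whose reads are shared with its near-identical copy EIF3C, stood at 124 ± 165 CPM with an SD above its mean. This comparison called 3434 genes, 2044 higher and 525 at least 2-fold, and 2123 in a fit of both groups alone. Mixture replicate 2 stood apart, with 11.9% of its counts mitochondrial against 8.13 and 9.22% in replicates 1 and 3. Its genes with no count in the vehicle summed to 66.7 CPM, against 20.9 and 24.6 CPM. Without both unusual libraries 3489 genes were called, and 2656 of the 3434 calls were shared in direction.

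The mixture was next set against BJIKT, both at 500 µg/mL in all. The mixture was higher for HLA-DPA1 by 2.95 ± 0.19, IL32 by 2.71 ± 0.16, CXCL9 by 2.49, CXCL10 by 1.85 ± 0.095 and the antiviral GTPase MX1 by 2.18 ± 0.35. In the mixture, 10 of 11 class II genes (10 adjusted over the list alone; camera adjusted p = 9.2e-56), 20 of 23 interferon genes (20 adjusted over the list alone; camera adjusted p = 1.24e-23) and 14 of 20 NF-kB targets were higher (15 higher and 1 lower when adjusted over the list alone; camera adjusted p = 2.09e-23). Of 24 cholesterol synthesis genes, 13 were higher and 2 lower (17 called when adjusted over the list alone; camera adjusted p = 1.59e-07), HMGCS1 by 0.67, and 13 of 21 mitosis genes were higher (14 adjusted over the list alone; camera adjusted p = 6.63e-08), BUB1 by 0.49. Complement C4A and C4B, near-identical copies, were higher by 2.54 and 2.63. The hypoxia-linked transcript MIR210HG was lower by 2.13 in the mixture and DDIT4 was lower by 1.39 ± 0.21. Of 25 hypoxia and glycolysis genes, 11 were lower and 1 higher (15 called when adjusted over the list alone; camera adjusted p = 0.000307, but 0.284 as the adjusted p with an estimated correlation), with CA9 at -0.93 (not called in a fit of both groups alone). Of 19 lysosome and autophagy genes, 7 were lower and 1 higher (11 called when adjusted over the list alone; camera adjusted p = 0.000277), with the sphingolipid activator PSAP at -0.47. Of NRF2 targets, 4 were higher and 1 lower of 19 (7 called when adjusted over the list alone; camera adjusted p = 0.385). This comparison called 3115 genes, 1555 higher and 1560 lower. The count was 1857 without BJIKT 500 replicate 1, 1863 without BJIKT 500 replicate 2 and 1851 without mixture replicate 2, and 447 in a fit of both groups alone.

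**Figure D3:**
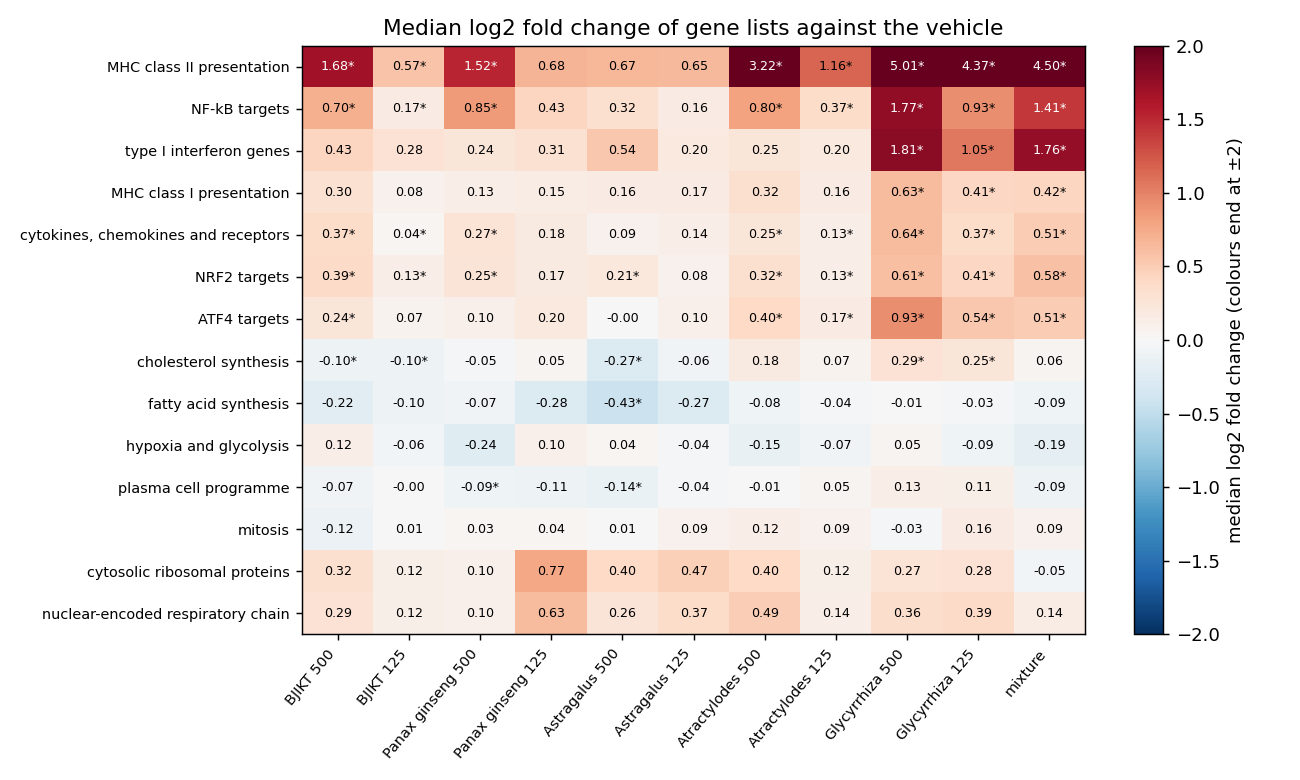
Median log2 fold change against the vehicle of 14 gene lists fixed before the data were examined (rows), for each extract and dose in µg/mL (columns). Colours end at ±2, and an asterisk marks an adjusted p under 0.05 from camera with an estimated correlation. MHC class II medians ran from 0.57 with BJIKT 125 to 5.01 with Glycyrrhiza 500.

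To compare the mixture with its parts, its log2 fold change was set against the sum of those of the 4 single herbs at 125 µg/mL, their dose in the mixture. The mixture lay below the sum, by a log2 difference of -5.57 ± 0.35 for CXCL10, -3.97 for IL32, -3.51 for LTB, -2.67 ± 0.25 for HLA-DRA, -1.51 for NQO1 and -1.40 for BIRC3. It lay above the sum for CIITA, by 1.65, a call that is lost without both unusual libraries, with the length trend removed, and without vehicle replicate 2 or Panax ginseng 125 replicate 1. Of 20 NF-kB targets, 10 lay below and 3 above (14 called when adjusted over the list alone; camera adjusted p = 0.0266, but 0.332 as the adjusted p with an estimated correlation), and 11 of 25 ATF4 targets lay below (11 adjusted over the list alone; camera adjusted p = 0.0117, but 0.328 as the adjusted p with an estimated correlation). All 34 ribosomal protein genes lay below (34 adjusted over the list alone; camera adjusted p = 2.38e-21, but 0.332 as the adjusted p with an estimated correlation); 33 of them were higher with Panax ginseng 125 and 28 with Astragalus 125. Differences were called for 5925 genes, 2898 above the sum and 3027 below. Without vehicle replicate 3 the count was 3732, and the vehicle enters this contrast as 3 times its own level, so its error weighs more than in the other comparisons.

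Across the 18025 genes, log2 fold changes of each group against the vehicle were set beside those of BJIKT 500. Pearson's r, across genes that are not independent replicates, was 0.628 for Glycyrrhiza 125, 0.605 for Atractylodes 500, 0.604 for Glycyrrhiza 500, 0.541 for BJIKT 125, 0.540 for the mixture, 0.538 for Panax ginseng 500, 0.518 for Atractylodes 125, 0.481 for Panax ginseng 125, 0.430 for Astragalus 500 and 0.424 for Astragalus 125. All 10 share the 3 vehicle libraries. In 20 simulations of unchanged groups against a shared simulated vehicle, the mean r was 0.50 with a covariance of 0.0326. Observed covariances ran from 0.111 for BJIKT 125 to 0.225 for Glycyrrhiza 500. The simulation drew each gene independently and computed log2 changes otherwise than the fit. Its values are therefore no exact reference for the observed ones. BJIKT 500 and Glycyrrhiza 500 shared 974 higher and 657 lower calls, where independent lists of those sizes would share 264 and 159, and 56 genes were called in opposite directions. With Atractylodes 500 the shared calls were 853 and 556 against 215 and 105, and with Panax ginseng 500 they were 152 and 81 against 14.7 and 6.55. Part of the excess may come from the shared vehicle libraries, which are too few to split.

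**Figure D4:**
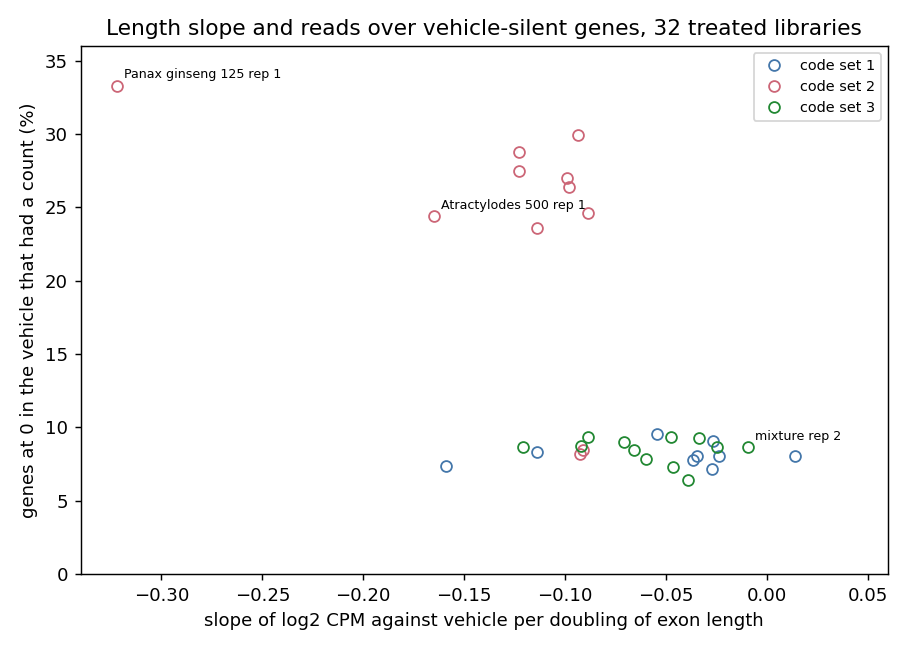
Slope of log2 CPM against the vehicle mean per doubling of exon length (horizontal) and share of the 3568 genes with no count in any vehicle library that had a count (vertical, %), for the 32 treated libraries, coloured by code set. Of code set 2, 9 libraries lie between 23.6 and 33.3% and every library of the other sets at 9.56% or below.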

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

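Of the tests below, those of dose effects between extracts were chosen after the data were seen, and so were the patterns weighed; each explanation's prediction was written down before its value was computed unless said otherwise.

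The effect of dose differed between extracts, which flagged the following results. Between BJIKT and Astragalus the difference of dose effects was called for 13 genes (edgeR, adjusted p under 0.05), CXCL10 at 1.68, CXCL9 at 1.29, HLA-DRA at 1.26 and PTPRG at -0.99. Between Glycyrrhiza and BJIKT it was called for 120 genes, C4A at 2.07, SESN2 at 0.90, ELL2 at 0.84, PSAT1 at 0.72, HLA-DRA at -0.90, CXCL9 at -0.98 and LINC00052 at -1.10. Between Glycyrrhiza and Astragalus it was called for 317 genes, CXCL8 at 2.19, PSAT1 at 1.10 and ELL2 at 0.95. These genes were chosen after their values were seen, and extracts of unlike code sets are compared through dose contrasts that each lie within 1 code set.

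Panax ginseng gave more calls at 125 (7521) than at 500 µg/mL (289). Without replicate 1 of the 125 group the count was 1133, under 0.5 of the full count, as predicted, after that value was known, if 1 library gave most of the calls. Fits without replicate 1 leave 1 library at 125, so their counts cannot be set against those at 500. In fits of only the groups compared the order turned, with 393 against 1884. The first of these takes part of its spread from 2 unlike libraries, so the turn does not decide the order. The 125 group lies in code set 2, while the 500 group and the vehicle lie in code set 1. Of genes with no count in the vehicle, 33.3 and 27% had a count in the 125 libraries, against 7.17 to 9.05% at 500. Dose and code set cannot be told apart here, so the cause is left open. Removal of the length trend left 5976 calls, 4644 of them shared in direction, so a smooth trend with exon length does not account for the count, and this prediction too came after. For a larger response at 125, the median ratio of changes with replicate 2 alone to those with replicate 1 alone was 0.366, but its genes were chosen in a fit with replicate 1, which lowers the ratio, so it cannot tell.

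Reads summed over the genes silent in the vehicle, a measure that no comparison uses, were flagged because up to 33.3% of the 3568 such genes had a count in 9 libraries of code set 2. Their silent genes summed to 50.7 to 129 CPM, against 10.5 to 66.7 CPM in other treated libraries, where at most 9.56% of the genes had a count. Reads spread along all gene bodies, such as genomic DNA, predicted counts that rise with exon length, and Spearman's rho was 0.551. Counts of RNA also rise with exon length, so rho cannot tell such reads from low-level RNA. RNA of another cell type predicted counts massed in few genes, but the 10 highest genes held 4.28%, and induction by the extracts predicted the signal in all Atractylodes 500 libraries, but its replicates 2 and 3 reached 8.49%. All 3 predictions were written after first values were seen, and the 9 libraries have consecutive code positions, 2 to 10.

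MHC class II and interferon genes rose most with Glycyrrhiza and the mixture, all in code set 3. A batch effect of that set predicted a like rise with Atractylodes 125, where the class II median was 1.16 against 4.37 with Glycyrrhiza 125, against the prediction, which was written after the values. The length trend does not account for it, as the Glycyrrhiza 500 median was 4.87 after its removal and 5.01 before. A response to Glycyrrhiza that is also present in the mixture fits: the median log2 difference of the mixture from Glycyrrhiza 125 was 0.359, again with the prediction written after. No Glycyrrhiza library lies in another code set, so a part played by the set cannot be excluded.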

How the results depend on the processing

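No named change turned its direction in any setting. Counts stayed within 1.5 times of the reported ones in all 18 comparisons with RLE scaling and with the length trend removed, in 14 with DESeq2, 12 without the low-count filter, 6 in fits of only the groups compared, and 68 of 117 fits that left out 1 library. The length trend and the omission of both unusual libraries were settings chosen after seeing the data. With DESeq2 the count was 178 for Atractylodes 125, and for dose contrasts 657 with BJIKT, 279 with Astragalus and 893 with Atractylodes. Without the filter, which tests more genes, it was 221 for BJIKT 125, 445 for Panax ginseng 500, 354 for Atractylodes 125, and for dose 1293 with BJIKT, 396 with Astragalus and 1430 with Atractylodes.

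In fits of only the groups compared it was 107 for BJIKT 125, 1884 and 393 for Panax ginseng 500 and 125, 5723 and 6200 for Astragalus 500 and 125, 832 for Atractylodes 125, 6630 for Glycyrrhiza 125, 2123 for the mixture, 447 for the mixture against BJIKT, and for dose 102 with BJIKT, 30 with Panax ginseng and 1476 with Astragalus. Such fits have fewer samples and their own dispersion. Without both unusual libraries it was 5028 and 118 for BJIKT 500 and 125, 592 and 1685 for Panax ginseng, 4869 and 5924 for Astragalus, 292 for Atractylodes 125, and for dose 2183 with BJIKT, 1008 with Panax ginseng, 546 with Astragalus, 2230 with Atractylodes and 1342 with Glycyrrhiza. Where no cause is named, the cause was not tested.

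Leaving out each library in turn, counts ranged from 896 to 4100 for BJIKT 500, 28 to 49 for BJIKT 125, 193 to 214 for Panax ginseng 500, 1133 to 9629 for Panax ginseng 125, 1419 to 2234 for Astragalus 500, 1721 to 2954 for Astragalus 125, 1958 to 4035 for Atractylodes 500, 38 to 56 for Atractylodes 125, 4434 to 5312 for Glycyrrhiza 500, 2365 to 3158 for Glycyrrhiza 125 and 2541 to 3791 for the mixture. For dose they ranged from 141 to 1452 with BJIKT, 575 to 9129 with Panax ginseng, 65 to 89 with Astragalus, 72 to 448 with Atractylodes and 547 to 641 with Glycyrrhiza, and were 1851 to 3909 for the mixture against BJIKT and 3732 to 8051 against the sum of the herbs. With 1 of the 2 Panax ginseng 125 libraries left out, the lone sample is assumed to vary like the other groups.

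The share of higher calls moved by over 10 points in several comparisons, and in some the balance turned. In the order DESeq2, no filter, fit of only the groups compared and both unusual libraries out, the BJIKT dose share went from 69.5% to 53.7%, 38.6%, 82.4% and 37.5%. Without the filter it went from 80.4% to 70.1% for BJIKT 125, from 88.8% to 48.3% for Atractylodes 125 and from 52.4% to 65.2% for the Astragalus dose, where DESeq2 gave 38.0%. In fits of only the groups compared it was 69.2% for BJIKT 125, 49.6% for Panax ginseng 500 (61.6% reported), 96.2% for Panax ginseng 125 (49.9%), 48.7% for Astragalus 500 (62.5%), 45.2% for Atractylodes 125 and 16.7% for the Panax ginseng dose (51.3%). Without both unusual libraries it was 50.7% for Panax ginseng 500, 82.8% for Panax ginseng 125, 71.9% for Atractylodes 125, 19.3% for the Panax ginseng dose and 41.4% for the Astragalus dose. With the length trend removed it was 47.1% for BJIKT 500 (58.4%), 51.2% for Panax ginseng 500, 76.7% for Atractylodes 125 and 56.6% for the BJIKT dose. Leaving out 1 library moved it to 68.8% for BJIKT 500, 83.1% for Panax ginseng 125, from 59.2% up to 74.4% for Astragalus 125, and for dose to 40.6% and 81.2% with BJIKT, 21.4% with Panax ginseng, 39.7% with Astragalus and from 66.5% up to 81.9% with Atractylodes. Among named genes, calls were lost in the fit of only the groups compared for CXCL8 with Panax ginseng 125, HLA-DRA and CIITA between its doses, CXCR5 with Panax ginseng 500, 7SK with Astragalus 125, RN7SL1 and RN7SL2 with Glycyrrhiza 125 and CA9 in the mixture against BJIKT. Leaving out 1 library ended a named call in 27 fits: 6 for ACSS2 and 5 for LSS with BJIKT 125, 4 for RN7SL1 and 2 for RN7SL2 with Glycyrrhiza 125, 3 for CXCR5 with Panax ginseng 500, 2 each for CHAC1 with Atractylodes 125, CYP1A1 with BJIKT 500 and CIITA in the mixture against the sum of the herbs, and 1 for RPPH1 with Panax ginseng 125. CIITA in that contrast lost its call with the length trend removed, as did its ATF4 and NF-kB lists (camera adjusted p = 0.0524 and 0.104). CIITA and RPPH1 lost theirs without both unusual libraries, LSS and ACSS2 without the filter, and CXCR5 with DESeq2. The plasma cell list with BJIKT 500 passed with RLE scaling (camera adjusted p = 0.0464) and with the length trend removed (0.00527), where the cholesterol list with Astragalus 125 passed as well (0.00275). In all, 261 list tests passed and 116 of them with an estimated correlation.

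With the replicate block, counts were 2624 for BJIKT 500, 54 for BJIKT 125 and 288 for Panax ginseng 500, and all other counts stayed within 1.5 times. The plasma cell list with BJIKT 500 passed with the block (camera adjusted p = 0.0379) and ACSS2 with BJIKT 125 lost its call, and no other named gene or list changed. Same-numbered samples did not deviate together: their deviations had a mean correlation of 0.000411 over 187 pairs, against -0.000197 over 374 other pairs. Deviations were taken from each group's own mean, which ties the mean over other pairs to that over same-numbered pairs. The other pairs are therefore no separate reference. For 14 of 35 samples, the mean correlation with samples of other groups was highest for their own replicate number, and some such matches arise without any pairing. Among 9117 genes above 10 CPM, r with BJIKT 500 was 0.759 for BJIKT 125, 0.733 and 0.749 for Panax ginseng 500 and 125, 0.756 and 0.697 for Astragalus, 0.820 and 0.697 for Atractylodes, 0.729 and 0.769 for Glycyrrhiza and 0.593 for the mixture, with 0.506 in simulated groups. For each group, r above 10 CPM was above its value over all genes. The simulated groups are no exact reference here either, since their genes were drawn independently. Depth limits genes near 1 CPM most, since 1 CPM is 22.8 counts in the smallest library.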

Other observations

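Glycyrrhiza at 500 µg/mL also moved genes of cell survival and hormone response. Of 6 oestrogen receptor targets, 3 rose and 1 fell (4 called when adjusted over the list alone, camera adjusted p = 0.000716), with the IGF-binding protein IGFBP4 at 3.33 ± 0.16 and the chemokine CXCL12 at 0.63. In the mixture 3 rose (4 adjusted over the list alone, camera adjusted p = 7.17e-06), IGFBP4 by 2.30 ± 0.16. Of 20 BCL2 family and caspase genes, 10 rose and 2 fell with Glycyrrhiza 500 (12 called when adjusted over the list alone, camera adjusted p = 0.00412). PMAIP1, which promotes cell death, rose by 1.38, the death inhibitors CFLAR and BCL2 rose by 0.81 and 0.84, and the death activator HRK fell by 1.18. Of 17 p53 targets, 6 rose and 1 fell (7 called when adjusted over the list alone, camera adjusted p = 0.019, but 0.0802 as the adjusted p with an estimated correlation), the death receptor FAS by 2.01 ± 0.086 and CDKN1A by 0.95. The kinase SGK1 rose by 2.24 and the epithelial transcription factor ELF3 by 3.67. The germinal centre regulator BCL6 rose by 1.97 and MS4A1, which encodes CD20, by 1.53, while BACH2 fell by 0.77 and the complement receptor CR2 fell by 1.00; the B cell list as a whole did not pass (camera adjusted p = 0.594).

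Iron handling and growth genes moved too. Of 10 iron handling genes, 4 rose and 1 fell with BJIKT 500 (6 called when adjusted over the list alone, camera adjusted p = 0.00136), the iron exporter SLC40A1 by 0.51. With Glycyrrhiza 500, 7 rose and 1 fell (8 called when adjusted over the list alone, camera adjusted p = 3.51e-06), FTH1 by 2.02. Of 22 DNA replication genes, 15 rose with Glycyrrhiza 500 (15 adjusted over the list alone, camera adjusted p = 0.000426, but 0.0794 as the adjusted p with an estimated correlation), CDC45 by 0.48. With Atractylodes 500, 9 of 21 MYC and ribosome biogenesis genes rose (9 adjusted over the list alone, camera adjusted p = 0.000664), RRP9 by 0.54. BJIKT 500 raised 7 of 19 lysosome and autophagy genes and lowered 1 (12 called when adjusted over the list alone, camera adjusted p = 0.00052), GABARAPL1 by 1.12. It raised 4 of 7 epithelial markers (4 adjusted over the list alone, camera adjusted p = 7.27e-05), KRT7 by 1.03 and CDH1 by 0.72. CYP1A1 rose by 1.03 with BJIKT 500 (not called without BJIKT 500 replicate 1 or vehicle replicate 3) and by 0.97 with Atractylodes 500, and fell by 1.32 in the mixture.

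The mixture was also set against Glycyrrhiza 125, a contrast within code set 3 that was chosen after the data were seen. It called 49 genes (30 higher and 19 lower, edgeR), where 3158 had an unadjusted p under 0.05, and 91 were called after removal of the length trend. Genes among the smallest adjusted p values, picked after their values were seen, were HMOX1 at 0.62, CXCL8 at 0.77, CXCL10 at 0.51, C4B at 1.00, CTSB at -0.35, HMGCS1 at -0.41 and TNFRSF17 at -0.88. Of 24 cholesterol synthesis genes, 3 were lower. Glycyrrhiza 500 against BJIKT 500, chosen in the same way, called 3606 genes (1754 higher and 1852 lower), with MT2A at 3.28, CXCL8 at 3.34, CXCL9 at 3.18, ELL2 at 1.64 and KRT15 at -1.35.

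A hypothesis was that effects of the single herbs add in CPM and not as log2 fold changes. It was prompted by CXCL10, and its prediction was written before the values. Over 237 genes at least 2-fold higher with Glycyrrhiza 125, the median log2 ratio of the mixture to the sum of single effects in CPM was -0.191 (quartiles -0.456 and 0.118). The ratio to the sum of log2 fold changes was -0.877 (quartiles -1.28 and -0.401), so the mixture lay closer to the sum in CPM over these genes. Without both unusual libraries the medians were -0.200 and -0.770. These genes were chosen by their rise with Glycyrrhiza 125, itself a term of the sum, and the mixture differed from Glycyrrhiza 125 in only 49 called genes. A mixture that acts like Glycyrrhiza alone could also lie near the sum in CPM, so the values cannot tell these apart. Single genes ran both ways, with CXCL10 at 215 CPM in the mixture against a sum of 189, CXCL9 at 374 against 315, HLA-DRA at 151 against 157 and MX1 at 246 against 161. LTB reached 52.6% and CIITA 214% of the sum.

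Every comparison of 6 libraries was repeated, in the fit of all 35 libraries, for all 10 ways to split them into 3 and 3. In 15 comparisons the real grouping was the only 1 of the 10 to reach its own count, and the highest other count was 0 genes in all but the mixture against BJIKT 500, where another split called 790 genes against the real 3115. The fit of these 6 libraries alone called 447. With 10 splits a share under 0.05 cannot be reached, and the predictions for the splits were written after the first counts were seen. Comparisons with Panax ginseng 125, and that of the mixture with the sum of the herbs, were not split.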
